A study of Mus musculus with 12 samples.

How the data were processed

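Total RNA (silica columns) from mouse embryonic stem cells was converted to Cy3-labelled cRNA by the submitters and hybridised to 12 whole mouse genome arrays, 1 sample per array. The scanner files hold spot signals as intensity per the file headers, background-subtracted and detrended within each array by Agilent Feature Extraction, together with per-spot flags, which are the other kind of value used here per the file headers. The submitters' notes give Feature Extraction 9.5.1.1, whereas the headers give 10.5.1.1 for undifferentiated cells, 10.7.3.1 for embryoid body (EB) days 1 and 3 and monolayer (ML) days 1 and 3, and 10.7.1.1 for EB day 4. The deposited value table holds intensity on a linear scale, and every column has the same quantiles (median 36.6, 75th percentile 488), so the authors equalised the distributions between arrays. Each column of it correlated at 0.998 to 1.000 with the scanner file of the same sample, and it was used as an alternative only.

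Main values were log2 of the processed signal minus the array's 75th percentile over 43379 non-control spots. Spots flagged as non-uniform or as population outliers were left out (51 to 172 per array), and no spot was saturated. Replicate spots were averaged into 41174 probes, of which 32 without a usable spot on at least 1 array were dropped. A probe was kept if both arrays of at least 1 group were well above background by the scanner software's flag, which left 26176. Gene symbols came from RefSeq accessions for 24828 probes, from a shared name for 4191 and from the files for 12123. Each gene was represented by its probe with the highest mean, giving 17764 genes, 14176 of them with a gene symbol. Probe positions are those of the files (build mm9). Signal over background sets the precision for dim genes, and the number of arrays limits it for all genes.

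Limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8) fitted 6 group means to all 12 arrays (6 residual degrees of freedom, prior degrees of freedom 3.19, prior SD 0.28) and tested 11 comparisons with its two-sided moderated statistic. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within the comparison. A fold change is given as at least N-fold, measured against the dim group's arrays raised to the lowest signal well above background on each, where 1 group was not well above background, and not at all where neither was, and folds that leaving out 1 array moves by at least 1.5 times are left as log2 changes. A difference between 2 changes is given as a bound where dim groups enter only against its direction, and not at all where another group is dim. Camera, from limma, tested 26 gene lists against all other genes with a preset correlation of 0.01, adjusted over the lists of a comparison. The lists covered pluripotency states, germ layers and extraembryonic lineages, signalling pathways, metabolism, stress, proliferation, Hox genes, markers of contaminating fibroblasts and sex-linked genes (Y-linked and Xist). Camera with a correlation estimated from the data and fry, which tests whether a set's genes move on balance one way, were run beside it. Calls within a list alone are given as adjusted over the list alone. Median log2 changes of all genes lay between -0.14 and 0.13, and changes are given without subtracting them.

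The text names genes only from those a rule selects: a panel of 16 marker genes called or not, the 5 largest increases and 5 largest decreases per comparison among called genes whose arrays separate the groups, and up to 4 called members of each list with the largest change. Not every selected gene is named, and 1 of them is not reported here. Comparisons, tests, lists, this rule and the alternative settings below were fixed before the data were examined. Alternative settings were normexp background (offset 50), quantile normalization, the authors' values, no filter or a strict filter on dim probes (well above background on all arrays), the mean of a gene's probes, a replicate block, a fit of the compared groups alone, a trended variance prior, and leaving out each array in turn. The fit of the 8 arrays of scan day 2 alone and the overlap with single arrays left out were added after seeing the data. Clone differences of 2 groups correlated between -0.154 and 0.227 across genes, so the clone number was checked as pairing in the replicate block but not used in the main analysis. Changes under 2 settings were compared as calls, and a count was taken as unmoved within 1.5-fold.

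Limma was tested on data simulated with each gene's measured spread, some of 17764 genes changing in EB day 3 against EB day 1. It recovered 5 of 67 genes changed by a log2 of 1, 50 of 67 by 2 and 65 of 66 by 3. It called 3 unchanged genes (2.44% of calls), and 118 genes with the replicate block. In a comparison without change it called 0. These rates ignore slide, scan day and unequal group spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.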

Results

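Mouse embryonic stem cells were profiled before and during differentiation, a series the submitters describe as gene expression related to epiblast development. Total RNA was hybridised to 12 arrays in 6 groups of 2. The groups were undifferentiated cells, whose sample titles name leukaemia inhibitory factor (LIF), embryoid bodies (EB) at days 1, 3 and 4, and monolayer cultures (ML) at days 1 and 3. Embryoid bodies are floating aggregates of differentiating cells, and LIF is the cytokine that keeps mouse embryonic stem cells undifferentiated through STAT3. The 2 arrays of a group carry the labels clone 1 and clone 2, and the submitters state 2 independent experiments per time point done by different people. No label names more than 2 independent cultures per group, so p-values below measure only array spread pooled over the groups fitted.

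Each array carried 43379 non-control spots, of which 52.1% to 63.8% were well above background, and the 75th percentile of the signal lay between 326 and 596 intensity units. Correlation across genes between the 2 arrays of a group ran from 0.971 (ML day 3) to 0.992 (EB day 1). ML day 3 had 3250 genes (18.3%) that differed at least 2-fold between its 2 arrays, and undifferentiated cells had 2125, against 603 (3.39%) in EB day 1. The file headers place the undifferentiated arrays on slide 1 and scan day 1, EB days 1 and 3 on slide 2 and ML days 1 and 3 on slide 4 (both scan day 2), and EB day 4 on slide 3 (scan day 3, another scanner). The undifferentiated and EB day 4 groups therefore cannot be told apart from their slide and scan day, whereas day 3 against day 1 was compared within a slide in both formats, and EB against ML across slides of 1 scan day. The E1A spike-in control spots averaged 1.09 to 1.29 log2 units brighter in the 4 groups of scan day 2 than in undifferentiated cells (at least 9 of 10 probes brighter in each), and 4 of 10 probes were brighter in EB day 4.

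Marker genes fixed in advance were followed (mean log2 signal relative to each array's 75th percentile ± SD, n = 2). Klf4, a transcription factor of the naive state (probe on chromosome 4, 55540833 to 55540892, build mm9), stood at 5.76 ± 0.16 in undifferentiated cells and at 1.97 ± 0.27 in EB day 1. Fgf5, a growth factor of the post-implantation epiblast (chromosome 5, 98705980 to 98706039), went from -2.04 ± 1.35 to 3.76 ± 0.42 in EB day 1 and 2.60 ± 0.27 in ML day 1. T (Brachyury), the primitive streak transcription factor (chromosome 17, 8634870 to 8634929), stood at -4.09 ± 0.59 in undifferentiated cells, 2.10 ± 0.14 in EB day 3 and 0.96 ± 0.17 in ML day 3. Sox17, a transcription factor of the endoderm (chromosome 1, 4481503 to 4481562), stood at 3.22 ± 0.65 in EB day 3 and -2.73 ± 1.25 in ML day 3. Sox1, an early neural gene, stayed between -4.34 ± 0.17 (EB day 3) and -3.69 ± 0.01 (ML day 1), was not well above background in EB day 4, and was not called in any comparison. Log2 changes below are given ± SE with n = 2 arrays per group.

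**Figure D1:**
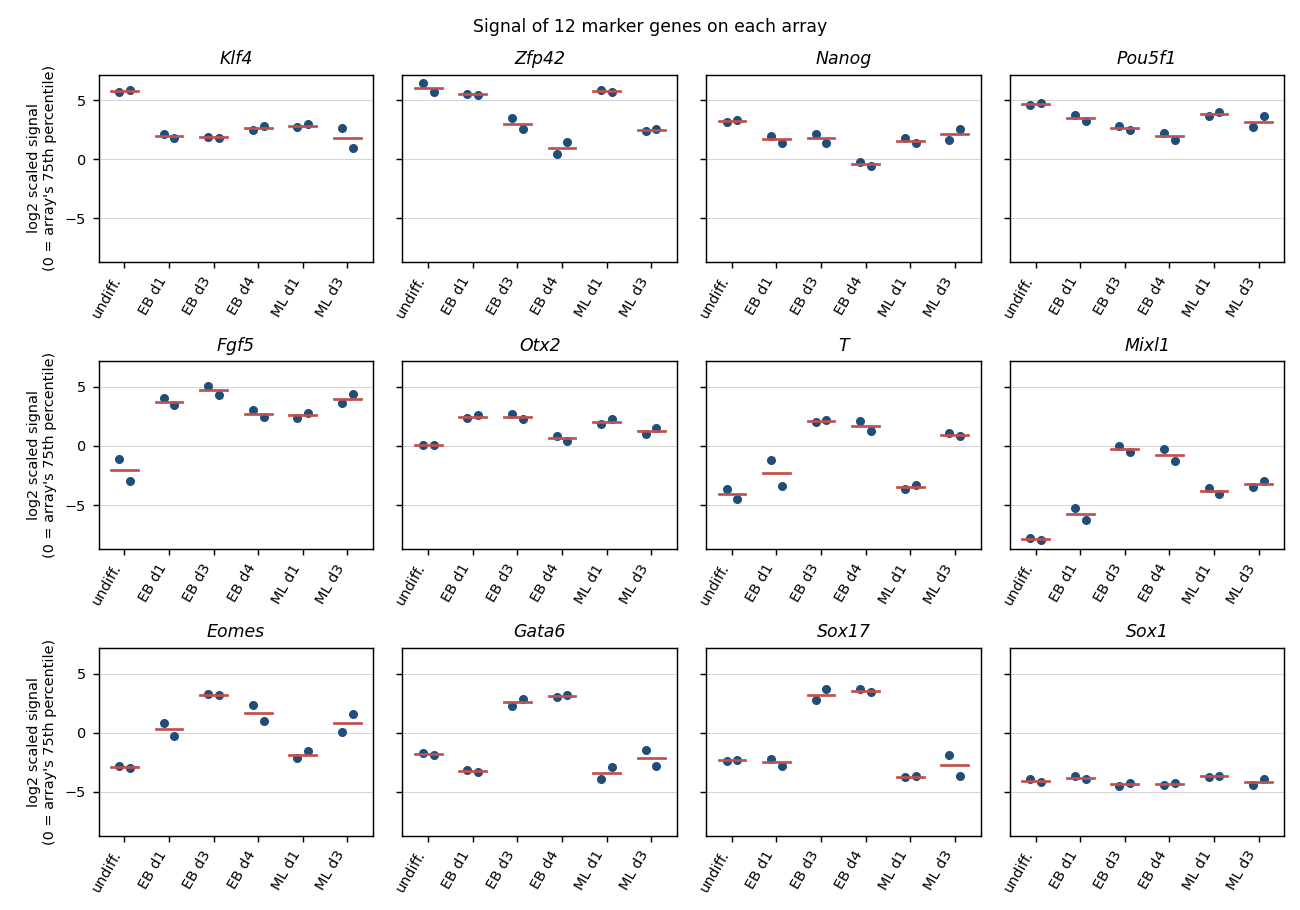
Log2 signal of 12 marker genes relative to each array's 75th percentile (vertical axis) in the 6 groups (horizontal axis); points are single arrays and red lines are means of 2 arrays. Sox17 and Gata6 are high in EB days 3 and 4 (Sox17 3.22 ± 0.65 in EB day 3), and Fgf5 is above -2.04 ± 1.35 in every differentiating group.

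Embryoid bodies at day 1 were compared with undifferentiated cells, from which they differ in culture, slide and scan day alike. Fgf5 rose (log2 change 5.80 ± 0.58, adjusted p = 0.00182) and Otx2, a homeobox factor of the epiblast, rose 5.14-fold (2.36 ± 0.28, adjusted p = 0.00339). Klf4 fell 13.9-fold (-3.79 ± 0.45, adjusted p = 0.00342), and so did Socs3, the feedback inhibitor of STAT3 signalling (-3.81 ± 0.27), Bcl3 (-3.09 ± 0.26) and the kinase gene Pim1 (-2.31 ± 0.31). Of the 13 measured LIF and STAT3 targets, 6 fell and 7 were not called (6 lower adjusted over the list alone). The LIF and STAT3 target median was -0.99 (camera adjusted p = 6.75e-07, adjusted p = 0.188 with an estimated correlation). The 20 measured formative and primed epiblast genes included 9 that rose, 1 that fell and 10 not called (10 higher and 1 lower adjusted over the list alone), with Zic2 (3.39 ± 0.29) beside Fgf5 and Otx2. The formative and primed epiblast median was 1.48 (camera adjusted p = 3.88e-05, adjusted p = 0.498 with an estimated correlation). Pou5f1 (-1.18 ± 0.34, adjusted p = 0.0511), Sox2 (-0.30 ± 0.35), Zfp42 (-0.56 ± 0.41) and T (1.80 ± 0.63) were not called. With 1 array left out the T change ran from 0.67 to 2.94, and T was called in part of these fits.

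Genes of the rare 2-cell-like state of embryonic stem cells were lower in EB day 1, with Zscan4c (-3.89 ± 0.38) and Usp17la (-2.34 ± 0.27). Among 7 measured 2-cell-like genes, 4 fell and 3 were not called (5 lower adjusted over the list alone), with a median of -2.34 (camera adjusted p = 0.000352, adjusted p = 0.396 with an estimated correlation). Among 20 measured naive pluripotency genes, 4 fell and 16 were not called (6 lower adjusted over the list alone), Klf4 showing the largest change, with a median of -0.73 (camera adjusted p = 0.000743, adjusted p = 0.489 with an estimated correlation, not called with fry). Beyond the lists, the largest increases included the neuropeptide gene Cck (5.50 ± 0.73) and Slc35d3 (4.27 ± 0.55), and the largest decreases the mesothelin gene Msln (-6.99 ± 0.70), Ankrd1 (at least 39.8-fold lower), the cardiac troponin gene Tnnt2 (at least 22.3-fold lower) and Klra7 (at least 15.9-fold lower). Of the 17 measured feeder fibroblast genes, 6 fell and 11 were not called (11 lower adjusted over the list alone), including Col1a2 (-2.65 ± 0.45). The feeder fibroblast median was -1.69 (camera adjusted p = 2.55e-05, adjusted p = 0.486 with an estimated correlation). In the undifferentiated group, 14 of these 17 fibroblast genes were higher in replicate 1 than in replicate 2, by a median of 0.95. Among 17764 genes, limma called 2371, 1415 higher and 956 lower. Leaving out single arrays moved this count to 788 (355 higher) without undifferentiated replicate 2, 204 (71 higher) without EB day 1 replicate 1 and 275 without EB day 1 replicate 2. The call ended for Col1a2 without EB day 1 replicate 2 (adjusted p up to 0.0725). Fitted on the groups compared alone, limma called 728 genes (314 higher), without Col1a2.

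Monolayer cultures at day 1 were set against the same undifferentiated cells. Fgf5 rose (4.63 ± 0.58, adjusted p = 0.00401), Zic2 rose (2.92 ± 0.29), and Mixl1, a homeobox gene of the primitive streak, rose at least 3.68-fold (adjusted p = 0.00252). Socs3 (-3.75 ± 0.27, adjusted p = 0.000631) and Bcl3 (-2.88 ± 0.26) fell, as did the immediate early gene Fos (-4.42 ± 0.57). Among 13 measured LIF and STAT3 targets, 6 fell and 7 were not called (6 lower adjusted over the list alone), with a median of -1.35 (camera adjusted p = 4.34e-07, adjusted p = 0.176 with an estimated correlation). Of the 20 measured formative and primed epiblast genes, 8 rose and 12 were not called (10 higher adjusted over the list alone). The formative and primed epiblast median was 1.25 (camera adjusted p = 0.00147, adjusted p = 0.756 with an estimated correlation, not called with fry). The 7 measured 2-cell-like genes included 3 that fell and 4 not called (3 lower adjusted over the list alone). The 2-cell-like median was -1.24 (camera adjusted p = 0.015, adjusted p = 0.729 with an estimated correlation, and adjusted p up to 0.194 without undifferentiated replicate 1, not called with fry). Of the 20 measured naive pluripotency genes, 3 fell and 17 were not called (1 higher and 3 lower adjusted over the list alone). The naive pluripotency median was -0.41 (camera adjusted p = 0.0431, adjusted p = 0.756 with an estimated correlation, and adjusted p up to 0.328 without undifferentiated replicate 1 or ML day 1 replicate 1, not called with fry). Pou5f1 (-0.83 ± 0.34), Sox2 (-0.42 ± 0.35), Zfp42 (-0.28 ± 0.41), Eomes (1.03 ± 0.59) and T (0.59 ± 0.63) were not called.

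The largest decreases in ML day 1 were Klra7 (at least 16.3-fold lower), Medag (at least 17.7-fold lower), Mgp (at least 16.1-fold lower), Casp4 (at least 18.6-fold lower) and Clec1b (at least 11.9-fold lower). Tac4 (at least 6.41-fold) and Lce1h (at least 3.97-fold) were among the largest increases. The 17 measured feeder fibroblast genes included 3 that rose, 1 that fell and 13 not called (3 higher and 3 lower adjusted over the list alone). The feeder fibroblast median was -0.62 (camera adjusted p = 0.47). Limma called 3196 genes, 2055 higher and 1141 lower. This count moved to 784 (379 higher) without undifferentiated replicate 2, 295 (146 higher) without ML day 1 replicate 1 and 292 (136 higher) without ML day 1 replicate 2. The median log2 change of all genes was 0.13, against 0.07 after quantile normalization. A fit of the groups compared alone called 277 genes (141 higher), without Fgf5 and Fos. The call ended with normexp background for Mixl1.

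The 2 culture formats were compared directly at day 1, within a scan day but across slides. Mgp, which encodes matrix Gla protein, was at least 16.1-fold higher in EB day 1 than in ML day 1 (adjusted p = 0.000423), the single gene called higher. The collagen gene Col8a1 was lower in EB day 1 (-3.58 ± 0.45, adjusted p = 0.034). No single gene among 10 measured definitive endoderm genes was called (5 higher adjusted over the list alone). The definitive endoderm median was 1.11 (camera adjusted p = 1.33e-07, adjusted p = 0.112 with an estimated correlation). Among 17 measured feeder fibroblast genes, 2 were lower and 15 were not called (6 lower adjusted over the list alone), with a median of -0.65 (camera adjusted p = 9.04e-07, adjusted p = 0.325 with an estimated correlation, not called with fry). Fgf5 (1.16 ± 0.58), Eomes (2.17 ± 0.59) and Sox17 (1.22 ± 0.52) were not called. Limma called 12 genes, 1 higher and 11 lower, against 1647 at an unadjusted p under 0.05. With 1 array left out it was 1 (1 higher) without EB day 1 replicate 1, 4 (3 higher) without EB day 1 replicate 2, 5 without ML day 1 replicate 1 and 1 (1 higher) without ML day 1 replicate 2. The call ended for Col8a1 without EB day 1 replicate 1 or 2 or ML day 1 replicate 1 or 2 (adjusted p up to 0.227). Fitted on the groups compared alone, limma called 3 genes (1 higher), without Col8a1. The call ended with no filter on dim probes for Col8a1 and with a replicate block for Col8a1.

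**Figure D2:**
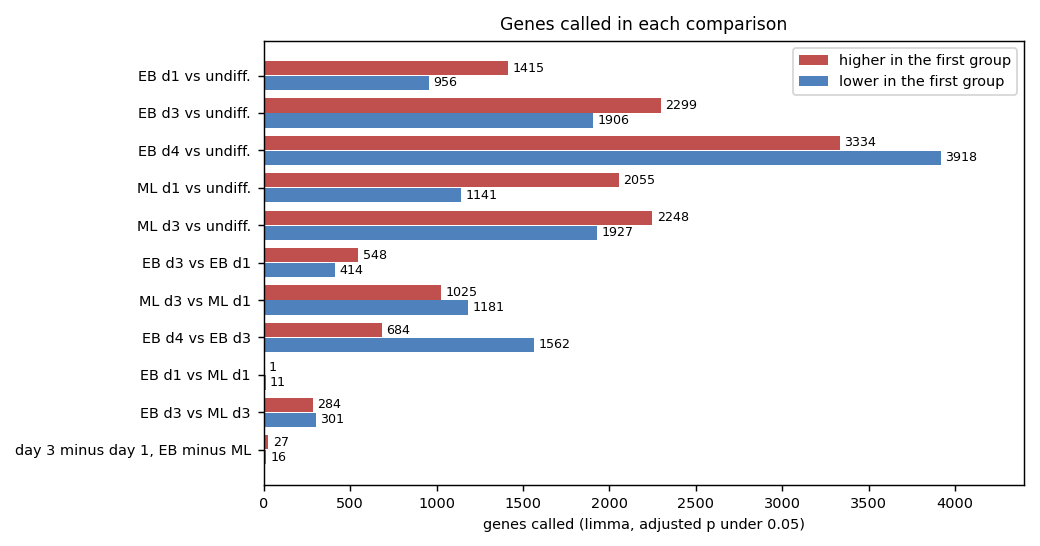
Number of genes called by limma at an adjusted p under 0.05 (horizontal axis) in each of the 11 comparisons (vertical axis), with genes higher (red) and lower (blue) in the first group named. EB day 4 against undifferentiated cells has the most calls (3334 and 3918) and EB day 1 against ML day 1 the fewest (1 and 11).

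Within the embryoid body slide, day 3 was compared with day 1 to follow the passage beyond the epiblast stage. Mesp1, a mesoderm regulator, rose (8.64 ± 0.68, adjusted p = 0.00118) and the homeobox gene Lhx1 rose (6.79 ± 0.56, adjusted p = 0.00123). Mixl1 rose at least 27.5-fold, Evx1 rose (5.72 ± 0.54) and T rose (4.39 ± 0.63, adjusted p = 0.00775). Among endodermal regulators, Gata6 rose 55.8-fold (5.80 ± 0.45, adjusted p = 0.00118), Sox17 rose 52.4-fold (5.71 ± 0.52), and Cer1, a secreted antagonist of Nodal, BMP and Wnt ligands, rose (6.07 ± 0.58). Of the 18 measured primitive streak and mesendoderm genes, 14 rose and 4 were not called (15 higher adjusted over the list alone). The primitive streak and mesendoderm median was 3.56 (camera adjusted p = 3.43e-19, and adjusted p = 0.0495 with an estimated correlation). The 10 measured definitive endoderm genes included 7 that rose and 3 not called (8 higher adjusted over the list alone), including Gsc (4.78 ± 0.59). The definitive endoderm median was 3.95 (camera adjusted p = 1.22e-10, and adjusted p = 0.0495 with an estimated correlation). Among 22 measured extraembryonic endoderm genes, 7 rose and 15 were not called (11 higher adjusted over the list alone), including the receptor gene Pdgfra (at least 25.5-fold), with a median of 1.27 (camera adjusted p = 2.21e-07, adjusted p = 0.0759 with an estimated correlation). Of the 14 measured canonical Wnt targets, 6 rose, 1 fell and 7 were not called (7 higher and 1 lower adjusted over the list alone), including the Wnt antagonist gene Dkk1 (5.59 ± 0.59). The canonical Wnt target median was 1.24 (camera adjusted p = 1.88e-06, and adjusted p = 0.0495 with an estimated correlation). Among 11 measured BMP targets, 4 rose and 7 were not called (8 higher and 1 lower adjusted over the list alone), including Msx1 (3.53 ± 0.32), with a median of 1.69 (camera adjusted p = 8.57e-05, adjusted p = 0.141 with an estimated correlation).

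Naive genes fell further in the same interval, among them Jam2 (-3.12 ± 0.34, adjusted p = 0.00295) and Zfp42 (-2.48 ± 0.41, adjusted p = 0.0132). Among 20 measured naive pluripotency genes, 8 fell and 12 were not called (1 higher and 12 lower adjusted over the list alone), with a median of -1.48 (camera adjusted p = 2.25e-07, adjusted p = 0.179 with an estimated correlation). The 18 measured mesoderm genes included 3 that rose and 15 not called (9 higher adjusted over the list alone). The mesoderm median was 1.49 (camera adjusted p = 1.88e-06, adjusted p = 0.285 with an estimated correlation, not called with fry). Among 18 measured Hox genes, 1 rose and 17 were not called (3 higher adjusted over the list alone), namely Hoxb3 (3.37 ± 0.41), with a median of 0.25 (camera adjusted p = 0.0234, adjusted p = 0.479 with an estimated correlation, and adjusted p up to 0.251 without EB day 3 replicate 2, not called with normexp background, the strict filter, the mean of probes or fry). Klf4 (-0.14 ± 0.45), Otx2 (0.03 ± 0.28), Fgf5 (0.96 ± 0.58) and Nanog (0.11 ± 0.37) were not called between days 1 and 3. Limma called 962 genes, 548 higher and 414 lower. Leaving out single arrays moved this count to 211 without EB day 1 replicate 1, 104 without EB day 1 replicate 2 and 108 without EB day 3 replicate 2. Calls ended for T without EB day 3 replicate 2 (adjusted p up to 0.0699) and Zfp42 without EB day 1 replicate 1 or 2 or EB day 3 replicate 2 (adjusted p up to 0.114). A fit of the groups compared alone called 660 genes (404 higher), without T. The call ended with the mean of probes for Hoxb3.

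In monolayers, day 3 was likewise compared with day 1 on one slide. T rose 22.1-fold (4.46 ± 0.63, adjusted p = 0.00377) and Fgf8, a growth factor gene of the primitive streak, rose 23.7-fold (4.56 ± 0.46, adjusted p = 0.00102). Jam2 (-4.00 ± 0.34), the nuclear receptor gene Nr5a2 (-3.66 ± 0.42) and Zfp42 (-3.28 ± 0.41, adjusted p = 0.00235) fell. Among 18 measured primitive streak and mesendoderm genes, 10 rose and 8 were not called (10 higher adjusted over the list alone), with a median of 1.67 (camera adjusted p = 1.38e-06, adjusted p = 0.313 with an estimated correlation). The 20 measured naive pluripotency genes included 14 that fell and 6 not called (15 lower adjusted over the list alone). The naive pluripotency median was -2.76 (camera adjusted p = 7.05e-08, adjusted p = 0.313 with an estimated correlation). Among 10 measured definitive endoderm genes, 4 rose and 6 were not called (4 higher adjusted over the list alone), including Cer1 (at least 4.65-fold), with a median of 1.12 (camera adjusted p = 0.00393, adjusted p = 0.313 with an estimated correlation). Mixl1 (0.59 ± 0.43, adjusted p = 0.379) and Sox17 (0.98 ± 0.52, adjusted p = 0.234) were not called. Of the 13 measured shared pluripotency genes, 4 fell and 9 were not called (5 lower adjusted over the list alone). The shared pluripotency median was -0.78 (camera adjusted p = 0.00859, adjusted p = 0.378 with an estimated correlation).

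Genes of the integrated stress response, which cells raise when protein synthesis is under strain, were a further group that rose in ML day 3. Vldlr, a lipoprotein receptor gene, rose (5.57 ± 0.73, adjusted p = 0.00276), and Chac1, which degrades glutathione, rose (4.94 ± 1.13, adjusted p = 0.0242), as did the transcription factor gene Atf3 (3.97 ± 0.73). Of the 15 measured integrated stress response genes, 10 rose and 5 were not called (11 higher adjusted over the list alone). The integrated stress response median was 1.30 (camera adjusted p = 1.38e-06, adjusted p = 0.313 with an estimated correlation). Its median was 1.00 without ML day 3 replicate 1, with 3 members called higher, and 1.69 without replicate 2, with 13 called higher and 1 lower. Calls ended for Chac1 without ML day 1 replicate 1 or 2 or ML day 3 replicate 1 (adjusted p up to 0.138) and Atf3 without ML day 1 replicate 2 (adjusted p up to 0.0941). The largest decreases were the endothelin gene Edn2 (-6.39 ± 0.74), Wfdc15a (at least 13.3-fold lower), the calcium channel gene Ryr3 (-5.12 ± 0.54), Capn3 (-5.12 ± 0.51) and Myo1g (-5.06 ± 0.30). Limma called 2206 genes, 1025 higher and 1181 lower. This count moved to 950 without ML day 1 replicate 1, 379 without ML day 1 replicate 2, 878 without ML day 3 replicate 1 and 4765 without ML day 3 replicate 2. The median log2 change of all genes was -0.14, and -0.05 after quantile normalization. Fitted on the groups compared alone, limma called 668 genes (260 higher), without Atf3. The call ended with normexp background for Cer1.

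The changes from day 1 to day 3 overlapped between the formats. Limma called 215 genes higher in both, against 31.6 for independent lists, and 299 lower in both, against 27.5, while 6 changed in opposite directions, against 60.3. Zfp42 (-2.48 ± 0.41 in EB and -3.28 ± 0.41 in ML) and T (4.39 ± 0.63 and 4.46 ± 0.63) moved alike. Across 17764 genes, which are not independent replicates, Pearson's r of the 2 sets of log2 changes was 0.597 and Spearman's rho 0.569. The number shared in direction was 514, and leaving out single arrays moved it to 118 (71 higher) without EB day 1 replicate 1, 46 (24 higher) without EB day 1 replicate 2, 47 (28 higher) without EB day 3 replicate 2, 342 without ML day 1 replicate 1, 196 without ML day 1 replicate 2 and 314 without ML day 3 replicate 1.

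**Figure D3:**
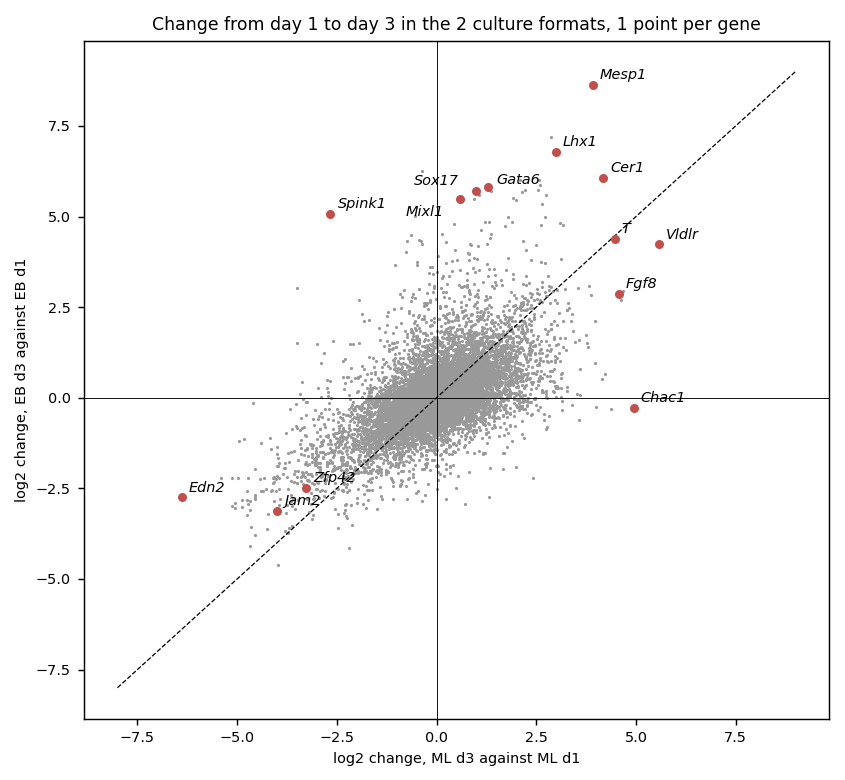
Log2 change of each of 17764 genes from day 1 to day 3 in monolayers (horizontal axis) and in embryoid bodies (vertical axis), 1 point per gene, with a dashed line of equal change. T lies on the line, Mixl1, Sox17 and Gata6 lie above it, and Chac1 and Vldlr lie below it; Pearson's r across genes is 0.597.

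At day 3 the embryoid bodies were compared with the monolayers across slides of the same scan day. Sox17 was higher in EB day 3 (5.95 ± 0.52, adjusted p = 0.00153), Cer1 54.9-fold (5.78 ± 0.58, adjusted p = 0.00238), the chemokine receptor gene Cxcr4 (5.36 ± 0.61), Foxa1 at least 7.85-fold, and Gata6 (4.70 ± 0.45). Lhx1 (5.18 ± 0.56), Mesp2 (3.47 ± 0.41), a segmentation gene, and Mixl1 (2.96 ± 0.43, adjusted p = 0.0104) were also higher in EB. Of the 10 measured definitive endoderm genes, 7 were higher and 3 were not called (9 higher adjusted over the list alone). The definitive endoderm median was 3.11 (camera adjusted p = 4.46e-12, and adjusted p = 0.0352 with an estimated correlation). The 18 measured primitive streak and mesendoderm genes included 8 that were higher, 1 that was lower and 9 not called (11 higher and 1 lower adjusted over the list alone). The primitive streak and mesendoderm median was 2.41 (camera adjusted p = 3.02e-08, adjusted p = 0.196 with an estimated correlation). Among 14 measured canonical Wnt targets, 2 were higher and 12 were not called (6 higher adjusted over the list alone), including Dkk1 (5.52 ± 0.59), with a median of 1.13 (camera adjusted p = 9.34e-06, adjusted p = 0.0972 with an estimated correlation). T (1.14 ± 0.63), Eomes (2.36 ± 0.59), Fgf5 (0.71 ± 0.58), Klf4 (0.02 ± 0.45) and Nanog (-0.31 ± 0.37) were not called.

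Lower in EB day 3 than in ML day 3 were Cth, an enzyme of cysteine synthesis (-2.12 ± 0.25, adjusted p = 0.00477), the kinase gene Pim1 (-2.53 ± 0.31), the actin-binding gene Tagln (-2.33 ± 0.26), and Edn1 and Thbs1, by at least 20.4-fold and 29.1-fold. Among 15 measured integrated stress response genes, 4 were lower and 11 were not called (12 lower adjusted over the list alone), with a median of -1.71 (camera adjusted p = 2.59e-08, adjusted p = 0.196 with an estimated correlation). Of the 17 measured feeder fibroblast genes, 5 were lower and 12 were not called (11 lower adjusted over the list alone). The feeder fibroblast median was -1.36 (camera adjusted p = 2.59e-08, adjusted p = 0.196 with an estimated correlation). The 13 measured LIF and STAT3 targets included 1 that was higher, 3 that were lower and 9 not called (1 higher and 4 lower adjusted over the list alone). The LIF and STAT3 target median was -0.61 (camera adjusted p = 0.00203, adjusted p = 0.196 with an estimated correlation, and adjusted p up to 0.172 without ML day 3 replicate 1). Among 25 measured hypoxia and glycolysis genes, 1 was higher and 24 were not called (11 higher adjusted over the list alone), with a median of 0.81 (camera adjusted p = 3.27e-06, adjusted p = 0.419 with an estimated correlation, not called with fry). Limma called 585 genes, 284 higher and 301 lower in EB. With 1 array left out it was 111 (71 higher) without EB day 3 replicate 2, 150 (99 higher) without ML day 3 replicate 1 and 2475 (1440 higher) without ML day 3 replicate 2. The call ended for Mixl1 without ML day 3 replicate 1 (adjusted p up to 0.071). Fitted on the groups compared alone, limma called 0 genes (1950 at an unadjusted p under 0.05).

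Whether the change from day 1 to day 3 differed between the formats was tested directly, as the EB change minus the ML change. The pancreatic trypsin inhibitor gene Spink1 had the largest difference among genes well above background in all 4 groups (7.74 ± 0.74, adjusted p = 0.013), and Gata6 (4.52 ± 0.64, adjusted p = 0.0286) and Sox17 (4.73 ± 0.73, adjusted p = 0.0444) rose more in EB. For Mixl1, not well above background in EB day 1, the rise in EB was at least 18.2-fold larger (adjusted p = 0.0286). T (-0.08 ± 0.89, adjusted p = 0.992), Eomes (0.19 ± 0.83) and Zfp42 (0.80 ± 0.58) did not differ past the threshold. Of the 18 measured primitive streak and mesendoderm genes, 2 rose more in EB and 16 were not called (8 higher and 2 lower adjusted over the list alone). The primitive streak and mesendoderm median was 2.11 (camera adjusted p = 7.85e-06, adjusted p = 0.233 with an estimated correlation, not called with fry). No single gene among 15 measured integrated stress response genes was called (7 lower adjusted over the list alone). The integrated stress response median was -1.33 (camera adjusted p = 5.39e-09, adjusted p = 0.233 with an estimated correlation, not called with fry). Limma called 43 genes, 27 with a larger change in EB and 16 with a smaller one, against 1809 at an unadjusted p under 0.05. Of the 43, 21 were well above background in all 4 groups, by any probe of the gene on at least 1 array, and 16 allow neither a value nor a bound. Leaving out single arrays moved this count to 0 without EB day 1 replicate 1, 0 without EB day 1 replicate 2, 85 without EB day 3 replicate 1, 6 without EB day 3 replicate 2, 2 without ML day 1 replicate 1, 0 without ML day 1 replicate 2, 14 without ML day 3 replicate 1 and 298 without ML day 3 replicate 2. With the strict filter the difference was higher in 12 genes and lower in 14. Calls ended for Spink1 without EB day 1 replicate 1 or 2 or ML day 1 replicate 2 (adjusted p up to 0.073), Mixl1 without EB day 1 replicate 1 or 2 or EB day 3 replicate 2 or ML day 1 replicate 1 or 2 or ML day 3 replicate 1 (adjusted p up to 0.136), Gata6 without EB day 1 replicate 1 or 2 or EB day 3 replicate 2 or ML day 1 replicate 1 or 2 (adjusted p up to 0.136) and Sox17 without EB day 1 replicate 1 or 2 or EB day 3 replicate 2 or ML day 1 replicate 1 or 2 (adjusted p up to 0.177). Fitted on the groups compared alone, limma called 9 genes (7 higher), without Gata6, Mixl1 and Sox17. The call ended with no filter on dim probes for Gata6, Mixl1 and Sox17, with the mean of probes for Gata6, with a replicate block for Gata6 and Sox17, with the 8 arrays of scan day 2 alone for Gata6, Mixl1 and Sox17, with quantile normalization for Sox17 and with the authors' values for Sox17.

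Against undifferentiated cells, EB day 3 combined lower naive genes with higher primitive streak and endoderm genes. Klf4 fell 15.3-fold (-3.93 ± 0.45, adjusted p = 0.000794), Zfp42 8.24-fold (-3.04 ± 0.41), and Jam2 (-4.79 ± 0.34), Tcl1 (-3.54 ± 0.37) and Pou5f1 (-2.01 ± 0.34, adjusted p = 0.0043) fell as well. Fgf5 rose (6.76 ± 0.58, adjusted p = 0.000218), T 73.1-fold (6.19 ± 0.63, adjusted p = 0.000512), Eomes 69.4-fold (6.12 ± 0.59) and Sox17 46.6-fold (5.54 ± 0.52). Cer1, at least 393-fold, Lhx1 (8.77 ± 0.56), Mesp1 (8.21 ± 0.68) and Gsc (7.74 ± 0.59) were among the 5 largest increases. Among 20 measured naive pluripotency genes, 15 fell and 5 were not called (16 lower adjusted over the list alone), with a median of -2.75 (camera adjusted p = 4.48e-09, adjusted p = 0.134 with an estimated correlation). The 18 measured primitive streak and mesendoderm genes included 14 that rose, 1 that fell and 3 not called (14 higher and 2 lower adjusted over the list alone). The primitive streak and mesendoderm median was 4.89 (camera adjusted p = 4.48e-09, adjusted p = 0.134 with an estimated correlation). Among 10 measured definitive endoderm genes, 8 rose and 2 were not called (9 higher adjusted over the list alone), with a median of 4.09 (camera adjusted p = 8.95e-08, adjusted p = 0.0804 with an estimated correlation). The 14 measured canonical Wnt targets included 7 that rose, 1 that fell and 6 not called (9 higher and 2 lower adjusted over the list alone), including Lgr5 (at least 42.6-fold). The canonical Wnt target median was 1.54 (camera adjusted p = 0.00143, adjusted p = 0.134 with an estimated correlation). Of the 13 measured LIF and STAT3 targets, 9 fell and 4 were not called (10 lower adjusted over the list alone). The LIF and STAT3 target median was -2.41 (camera adjusted p = 7.39e-08, adjusted p = 0.0804 with an estimated correlation).

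The meiosis gene Stra8 (-7.66 ± 0.54), Tm4sf1 (-7.17 ± 0.89), S100a4 (-6.63 ± 0.70) and Msln (at least 349-fold lower) were among the largest decreases in EB day 3. Among 20 measured formative and primed epiblast genes, 10 rose and 10 were not called (10 higher adjusted over the list alone), with a median of 0.90 (camera adjusted p = 0.00248, adjusted p = 0.652 with an estimated correlation). Of the 7 measured 2-cell-like genes, 5 fell and 2 were not called (5 lower adjusted over the list alone). The 2-cell-like median was -2.63 (camera adjusted p = 0.000913, adjusted p = 0.172 with an estimated correlation). The 11 measured BMP targets included 5 that rose and 6 not called (5 higher and 1 lower adjusted over the list alone). The BMP target median was 0.61 (camera adjusted p = 0.0367, adjusted p = 0.458 with an estimated correlation, and adjusted p up to 0.0824 without undifferentiated replicate 2 or EB day 3 replicate 2, not called with the strict filter or the compared groups alone). Among 17 measured feeder fibroblast genes, 12 fell and 5 were not called (12 lower adjusted over the list alone), including Dcn (-3.79 ± 0.59), with a median of -2.32 (camera adjusted p = 4.34e-06, adjusted p = 0.237 with an estimated correlation). Limma called 4205 genes, 2299 higher and 1906 lower. This count moved to 2580 without undifferentiated replicate 2, 2558 (1265 higher) without EB day 3 replicate 1 and 1832 without EB day 3 replicate 2.

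ML day 3 was likewise compared with undifferentiated cells. Fgf5 rose (6.05 ± 0.58, adjusted p = 0.000475), Wnt3, a ligand needed for the primitive streak, 37.3-fold (5.22 ± 0.44, adjusted p = 0.000297), T 33.2-fold (5.05 ± 0.63), Fgf8 (4.73 ± 0.46) and Gsc (5.14 ± 0.59). Zfp42 fell 11.8-fold (-3.56 ± 0.41, adjusted p = 0.000873), Klf4 (-3.95 ± 0.45), Esrrb 15.5-fold (-3.96 ± 0.60) and Jam2 (-5.48 ± 0.34). Sox17 (-0.40 ± 0.52), Gata6 (-0.33 ± 0.45) and Nanog (-1.15 ± 0.37, adjusted p = 0.0517) were not called. Of the 20 measured naive pluripotency genes, 14 fell and 6 were not called (17 lower adjusted over the list alone). The naive pluripotency median was -3.12 (camera adjusted p = 1.87e-10, adjusted p = 0.345 with an estimated correlation). Among 18 measured primitive streak and mesendoderm genes, 11 rose and 7 were not called (11 higher and 1 lower adjusted over the list alone), with a median of 3.45 (camera adjusted p = 0.000132, adjusted p = 0.51 with an estimated correlation). The 15 measured integrated stress response genes included 8 that rose, 1 that fell and 6 not called (10 higher and 1 lower adjusted over the list alone). The integrated stress response median was 1.42 (camera adjusted p = 0.00126, adjusted p = 0.59 with an estimated correlation). Among 7 measured 2-cell-like genes, 4 fell and 3 were not called (5 lower adjusted over the list alone), with a median of -2.57 (camera adjusted p = 0.00718, adjusted p = 0.51 with an estimated correlation). The 13 measured LIF and STAT3 targets included 7 that fell and 6 not called (8 lower adjusted over the list alone). The LIF and STAT3 target median was -1.39 (camera adjusted p = 0.000389, adjusted p = 0.345 with an estimated correlation). Of the 17 measured feeder fibroblast genes, 3 rose, 7 fell and 7 were not called (3 higher and 8 lower adjusted over the list alone). The feeder fibroblast median was -0.94 (camera adjusted p = 0.184). Limma called 4175 genes, 2248 higher and 1927 lower. With 1 array left out it was 2378 without undifferentiated replicate 2 and 2655 without ML day 3 replicate 1.

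EB day 4, on its own slide and scan day, had the most called genes against undifferentiated cells. Esrrb fell (-6.46 ± 0.60, adjusted p = 0.000118), Zfp42 33.8-fold (-5.08 ± 0.41), Sox2 26.2-fold (-4.71 ± 0.35, adjusted p = 4.8e-05), Nanog 12.6-fold (-3.65 ± 0.37) and Pou5f1 6.61-fold (-2.72 ± 0.34). Hand1, a regulator of heart and extraembryonic mesoderm, rose 353-fold (8.46 ± 1.08, adjusted p = 0.000458), Isl1, a marker of cardiac progenitors, 46.5-fold (5.54 ± 0.55), Tbx20 at least 25.4-fold and Mesp1 679-fold (9.41 ± 0.68). Sox17 (5.89 ± 0.52), Foxa2 (6.38 ± 0.68) and T (5.76 ± 0.63) were higher too, as were the BMP target Msx1 (5.69 ± 0.32) and Dkk1 (6.73 ± 0.59). The 20 measured naive pluripotency genes included 1 that rose and 19 that fell (1 higher and 19 lower adjusted over the list alone). The naive pluripotency median was -4.29 (camera adjusted p = 1.47e-09, adjusted p = 0.142 with an estimated correlation). Among 18 measured mesoderm genes, 15 rose, 2 fell and 1 was not called (16 higher and 2 lower adjusted over the list alone), with a median of 3.08 (camera adjusted p = 1.08e-05, adjusted p = 0.292 with an estimated correlation). Of the 18 measured primitive streak and mesendoderm genes, 15 rose, 1 fell and 2 were not called (15 higher and 2 lower adjusted over the list alone). The primitive streak and mesendoderm median was 4.13 (camera adjusted p = 2.39e-07, adjusted p = 0.154 with an estimated correlation). The 10 measured definitive endoderm genes included 9 that rose and 1 not called (9 higher adjusted over the list alone). The definitive endoderm median was 5.23 (camera adjusted p = 4.38e-07, adjusted p = 0.142 with an estimated correlation). Among 11 measured BMP targets, 8 rose, 1 fell and 2 were not called (8 higher and 1 lower adjusted over the list alone), with a median of 2.48 (camera adjusted p = 0.00028, adjusted p = 0.154 with an estimated correlation).

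Of the 13 measured shared pluripotency genes, 7 fell and 6 were not called (7 lower adjusted over the list alone). The shared pluripotency median was -1.68 (camera adjusted p = 0.011, adjusted p = 0.337 with an estimated correlation, and adjusted p up to 0.0674 without undifferentiated replicate 1). Among 14 measured canonical Wnt targets, 9 rose, 1 fell and 4 were not called (9 higher and 1 lower adjusted over the list alone), with a median of 2.44 (camera adjusted p = 0.000595, adjusted p = 0.142 with an estimated correlation). The 22 measured extraembryonic endoderm genes included 11 that rose, 3 that fell and 8 not called (12 higher and 3 lower adjusted over the list alone). The extraembryonic endoderm median was 1.28 (camera adjusted p = 0.0086, adjusted p = 0.292 with an estimated correlation, not called with no filter on dim probes). Among 17 measured feeder fibroblast genes, 12 fell and 5 were not called (13 lower adjusted over the list alone), including Col3a1 (-3.41 ± 0.56), with a median of -1.82 (camera adjusted p = 0.00018, adjusted p = 0.292 with an estimated correlation). Among 13 measured LIF and STAT3 targets, 9 fell and 4 were not called (10 lower adjusted over the list alone), with a median of -3.13 (camera adjusted p = 2.15e-05, adjusted p = 0.142 with an estimated correlation). Otx2 (0.54 ± 0.28) and Dnmt3b (0.05 ± 0.55) were not called. Limma called 7252 genes, 3334 higher and 3918 lower. Leaving out single arrays moved this count to 4660 without EB day 4 replicate 1 and 4708 without EB day 4 replicate 2. The balance of direction turned with normexp background, the strict filter and no filter on dim probes.

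Between EB days 3 and 4, which were scanned on different days and scanners, pluripotency genes fell further and several mesodermal genes rose. Sox2 fell 8.21-fold (-3.04 ± 0.35, adjusted p = 0.00251), the epiblast genes Zic2 (-2.72 ± 0.29) and Pim2 (-3.03 ± 0.38) fell, and so did Nodal, a ligand of the transforming growth factor family (-2.25 ± 0.33, adjusted p = 0.00598). Isl1 rose (4.03 ± 0.55, adjusted p = 0.0045), and the complement lectin gene Colec11 rose at least 20.7-fold. T (-0.43 ± 0.63), Mixl1 (-0.50 ± 0.43), Sox17 (0.34 ± 0.52) and Gata6 (0.57 ± 0.45) were not called. The 18 measured mesoderm genes included 7 that rose and 11 not called (10 higher adjusted over the list alone). The mesoderm median was 1.96 (camera adjusted p = 2.77e-07, adjusted p = 0.319 with an estimated correlation). Of the 20 measured formative and primed epiblast genes, 7 fell and 13 were not called (11 lower adjusted over the list alone). The formative and primed epiblast median was -1.44 (camera adjusted p = 0.000792, adjusted p = 0.501 with an estimated correlation). Among 13 measured shared pluripotency genes, 6 fell and 7 were not called (7 lower adjusted over the list alone), with a median of -0.96 (camera adjusted p = 0.00071, adjusted p = 0.319 with an estimated correlation). The 20 measured naive pluripotency genes included 1 that rose, 11 that fell and 8 not called (1 higher and 14 lower adjusted over the list alone). The naive pluripotency median was -1.59 (camera adjusted p = 5.1e-05, adjusted p = 0.319 with an estimated correlation). Of the 18 measured Hox genes, 7 rose, 1 fell and 10 were not called (8 higher and 2 lower adjusted over the list alone). The Hox gene median was 1.78 (camera adjusted p = 0.00071, adjusted p = 0.346 with an estimated correlation, not called with no filter on dim probes, the strict filter or fry). The 11 measured BMP targets included 6 that rose and 5 not called (6 higher adjusted over the list alone). The BMP target median was 1.47 (camera adjusted p = 0.00071, adjusted p = 0.319 with an estimated correlation, not called with no filter on dim probes). Among 11 measured Nodal and Activin pathway genes, 5 fell and 6 were not called (5 lower adjusted over the list alone), with a median of -0.76 (camera adjusted p = 0.0136, adjusted p = 0.319 with an estimated correlation, not called with the compared groups alone).

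The largest decreases at day 4 were Cdk5r2 (-5.89 ± 0.24), Mchr1 (-5.23 ± 0.41), Vps13a (-4.43 ± 0.40), Arid5b (-4.53 ± 0.29) and Synpo (-3.90 ± 0.27), and other probes of Arid5b and Synpo changed in the opposite direction. Limma called 2246 genes, 684 higher and 1562 lower. This count moved to 338 without EB day 3 replicate 1, 853 without EB day 4 replicate 1 and 566 without EB day 4 replicate 2. The majority turned with normexp background and with no filter on dim probes. Of called genes with another probe, 17.4% had one of opposite sign, against 3.14% in EB day 3 against day 1. The 5 comparisons with undifferentiated cells had 14.6% to 21.6%, which limits those calls. Fitted on the groups compared alone, limma called 239 genes (71 higher), without Colec11, Isl1, Nodal, Pim2 and Sox2. The call ended with the mean of probes for Arid5b and Synpo.

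**Figure D4:**
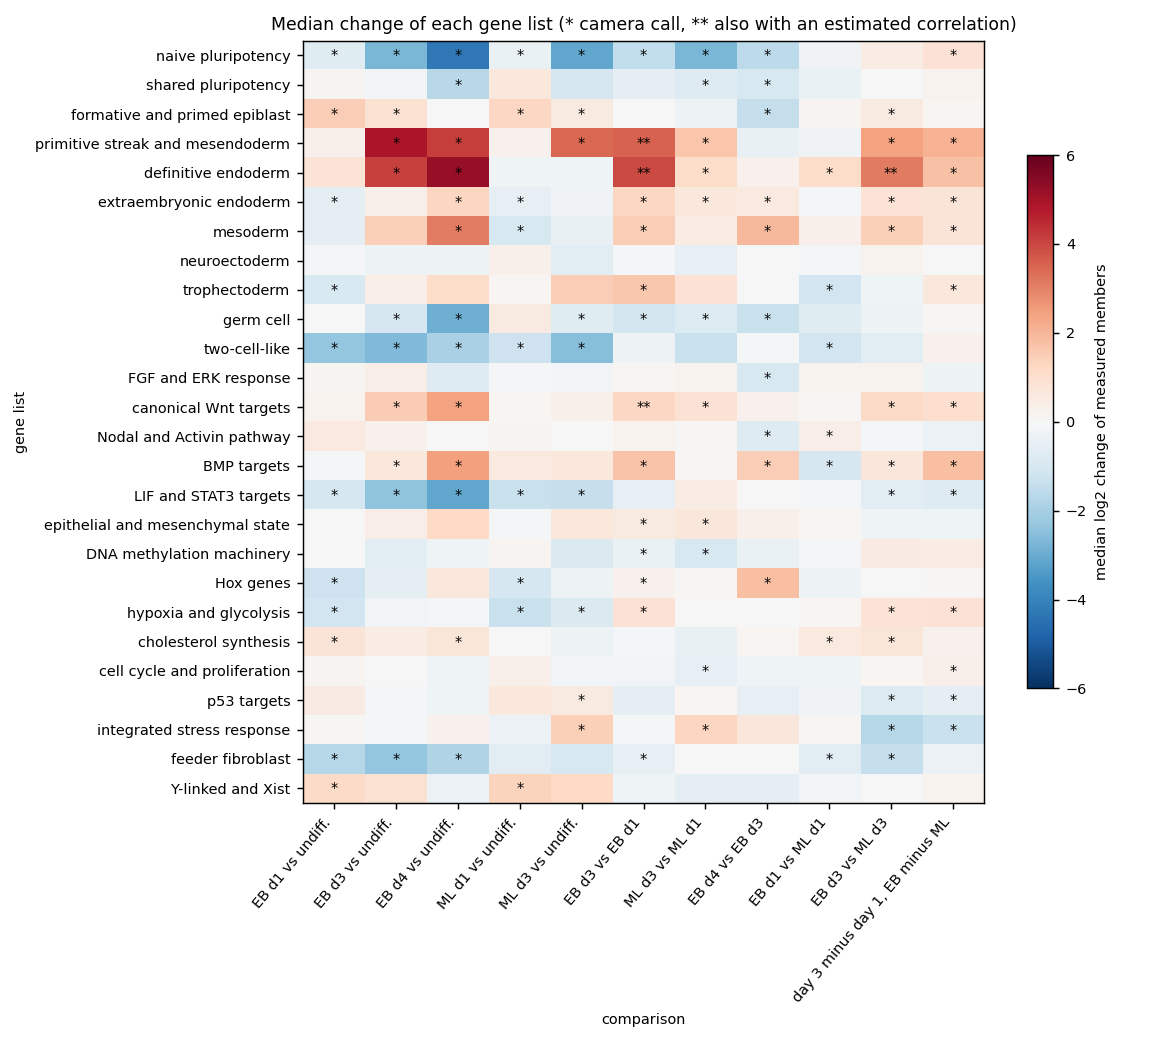
Median log2 change (colour) of the measured members of 26 gene lists (vertical axis) in the 11 comparisons (horizontal axis); 1 star marks a camera call and 2 stars a call that also held with an estimated correlation. The naive pluripotency list is lowest in EB day 4 against undifferentiated cells (-4.29), and definitive endoderm is highest there (5.23).

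Across the 286 tests of 26 lists in 11 comparisons, camera called 120 with its preset correlation, and 4 of these also passed with an estimated correlation. These were primitive streak and mesendoderm, definitive endoderm and canonical Wnt targets in EB day 3 against EB day 1, and definitive endoderm in EB day 3 against ML day 3.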

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

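Among the tests of explanations here, the scan-day tests of the fibroblast genes, both tests of the stress genes and the test of called genes with opposite probes were chosen after the results were seen. The rules of the scan-day and divergent-array tests were changed 2 times after their values were seen: a camera call alone argued against both explanations, a call with an estimated correlation, which both lists also miss with all arrays, was then asked for too and left both open, and fry now takes its place, also in the test of formats, with the scan-day test split by day.

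The change from day 1 to day 3 differed between embryoid bodies (EB) and monolayers (ML) in 43 genes by limma's test of that difference (EB change minus ML change, log2 ± SE). Of these, 21 were well above background in all 4 groups (any probe of the gene on at least 1 array), 6 give only a bound, and 16 give neither a value nor a bound and are not named. Spink1 (7.74 ± 0.74), Sox17 (4.73 ± 0.73), Gata6 (4.52 ± 0.64), Mesp2 (4.14 ± 0.59) and Msx1 (2.95 ± 0.45) changed more upward in EB, as did Pga5 by at least 75.5-fold and Mixl1 by at least 18.2-fold. H2-D4 (-2.47 ± 0.38) and H2-Q10 (-2.33 ± 0.31) changed more upward in ML. Limma called 0 genes without EB day 1 replicate 1, EB day 1 replicate 2 or ML day 1 replicate 2 (1306, 1269 and 1244 at an unadjusted p under 0.05), so each of these calls ended there. No filter on dim probes and the fit of the compared groups, the 8 arrays of scan day 2, ended the call of each gene named here except Spink1, the replicate block those of Sox17, Gata6, Mesp2, Msx1 and H2-D4, the mean of probes those of Gata6 and H2-Q10, and quantile normalization or the authors' values those of Sox17 and Msx1. With another array left out the count ran from 2 (ML day 1 replicate 1) to 298 (ML day 3 replicate 2).

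Camera called 13 gene lists in the same test (median log2 difference, EB change minus ML change). The difference in change was positive for primitive streak and mesendoderm (2.11), BMP targets (1.79), definitive endoderm (1.74), canonical Wnt targets (0.99), hypoxia and glycolysis (0.87), naive pluripotency (0.87), mesoderm (0.78), extraembryonic endoderm (0.77), trophectoderm (0.64) and cell cycle and proliferation (0.30). It was negative for the integrated stress response (-1.33), LIF and STAT3 targets (-0.79) and p53 targets (-0.57). A positive value is not a higher level in EB: the naive pluripotency median fell in both formats, and fell less in EB. Their camera adjusted p ran from 5.39e-09 to 0.0378, and none was called by fry or with an estimated correlation (adjusted p = 0.233 to 0.655 with an estimated correlation). Normexp background ended the calls of trophectoderm and of cell cycle and proliferation, the strict filter those of mesoderm and trophectoderm, quantile normalization that of cell cycle, and the fit of the compared groups, the 8 arrays of scan day 2, that of trophectoderm. Calls with the preset correlation ended, with the highest adjusted p in parentheses, for naive without EB day 3 replicate 1 or ML day 3 replicate 2 (0.114), extraembryonic endoderm without ML day 3 replicate 2 (0.167), mesoderm without EB day 3 replicate 2 or ML day 3 replicate 2 (0.55), trophectoderm without EB day 1 replicate 2 or EB day 3 replicate 2 or ML day 1 replicate 1 or ML day 3 replicate 2 (0.473), Wnt without ML day 3 replicate 2 (0.112), BMP without ML day 3 replicate 2 (0.104), LIF without ML day 3 replicate 1 (0.16), hypoxia without EB day 3 replicate 2 (0.0708), cell cycle without EB day 1 replicate 2 or EB day 3 replicate 1 or ML day 1 replicate 2 or ML day 3 replicate 1 (0.576) and p53 without ML day 3 replicate 1 (0.154).

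The E1A spike-in spots, outside the gene comparisons, differed between groups: relative to each array's 75th percentile they averaged at least 1.09 log2 units brighter over 10 probes in each group of scan day 2 than in undifferentiated cells, and averaged 0.69 on ML day 3 replicate 1 against 1.23 on replicate 2.

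Feeder fibroblast genes were lower in EB than in undifferentiated cells (12 of 17 called lower in EB day 3), and Col1a2 averaged 3.03 in undifferentiated cells and 0.38 in EB day 1. In a second list of 31 fibroblast genes, all well above background in undifferentiated cells and 21 of them in EB day 3, 14 were called lower in EB day 3 and 1 higher, too few for the loss of fibroblasts and too many to argue against it by the rule fixed before that list was looked at. In EB against ML of 1 scan day, the feeder median was -1.36 at day 3, with 5 called lower. Adjusted p was 2.59e-08 by camera, 0.0195 by fry and 0.196 with an estimated correlation. At day 1 the median was -0.65, with 2 called lower (adjusted p = 0.106 by fry and 0.325 with an estimated correlation). The second list had -0.24 and 0.15 at days 3 and 1. Higher levels in ML would give -1.36 too, so the scan day stays open. Within the undifferentiated slide, replicate 1 exceeded replicate 2 in 14 of 17 feeder genes (median 0.95) and 23 of 31 genes of the second list (1.04), against 0.03 for all genes. Loss of fibroblasts, the scan day, the slide and a change of these genes in the differentiating cells, the last 2 not tested, cannot be told apart, since the undifferentiated arrays share 1 slide, EB and ML lie on different slides and the labels name no feeder layer.

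Integrated stress response genes were higher in ML day 3 than in ML day 1 (10 of 15 called, median 1.30). The list was called by camera and by fry without either ML day 3 array, but not with an estimated correlation. Its median was 1.00 without replicate 1 and 1.69 without replicate 2, so a higher median did not rest on 1 of these arrays alone. The rule for a single divergent array was set with these values known, so it gives no verdict on how much replicate 1 adds. A response that may differ between formats would lower the list in the EB change minus the ML change, where the median was -1.33 (camera adjusted p = 5.39e-09, adjusted p = 0.0859 by fry, adjusted p = 0.233 with an estimated correlation). Whether the formats differ stays open, since camera called that test and fry did not. No other biological explanation was tested.

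Limma called 2246 genes between EB days 3 and 4, and as few as 338 with 1 array left out. Log2 changes of both probes of a gene correlated at 0.540 across 6136 genes in that comparison, against 0.765 and 0.754 within the EB and ML slides, 0.586 to 0.683 against undifferentiated cells, also across scan days, and 0.656 and 0.798 for EB against ML at days 1 and 3, which is consistent with probe-specific differences between scan days as 1 source of calls. Among called genes with another probe, 17.4% had it change in the opposite direction, against 3.14% and 6.52% within slides (Fisher's exact p = 1.01e-10 and 7.69e-10, two-sided) and 14.6% to 21.6% against undifferentiated cells. Genes are not independent replicates, the called changes were smaller than within slides (median 1.25 against 1.71 and 1.45 log2 units), and isoforms that change from day 3 to day 4 could also separate probes of a gene. How many of the 2246 calls come from the day and how many from the scan stays open, since EB day 4 has a slide and scan day of its own.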

How the results depend on the processing

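All alternatives here were planned except the fit of the 8 arrays of scan day 2 and the overlap with single arrays left out, which were chosen after seeing the data. With normexp background, quantile normalization or the authors' values, the number of called genes in each of the 11 comparisons, the overlap and the number of called lists stayed within 1.5-fold. The balance of higher and lower genes turned in places: with normexp background 3698 genes were higher and 2562 lower in EB day 4 against undifferentiated cells (3334 and 3918) and 1724 and 1197 against day 3 (684 and 1562, 1323 calls shared), and in ML day 3 against day 1 quantile normalization gave 1043 and 956 and the authors' values 1073 and 941 (1025 and 1181). It turned as well with the mean of probes in EB day 3 and ML day 3 against undifferentiated cells, with 1987 and 2073 (2299 and 1906) and 2029 and 2097 (2248 and 1927) and with the strict filter in EB day 4 against undifferentiated cells (2824 and 2517) and in ML day 3 against day 1 (917 and 913), and in the difference in change (12 and 14, against 27 and 16), with the compared groups alone in EB day 1 (314 and 414, against 1415 and 956) and ML day 3 against undifferentiated cells (422 and 540), with the 8 arrays of scan day 2 in EB against ML at day 3 (231 and 218, against 284 and 301), and in several fits with 1 array left out. Moved counts are given with the number as reported in parentheses, and where no reason is given the cause was not tested. A fit of the compared groups alone has fewer degrees of freedom. It called 728 genes (2371) in EB day 1 and 1635 (4205) in EB day 3, 277 (3196) in ML day 1 and 962 (4175) in ML day 3, each against undifferentiated cells. It called 668 (2206) in ML day 3 against day 1, 239 (2246) in EB day 4 against day 3, 3 (12) in EB against ML at day 1, 0 (585) at day 3 (1950 at an unadjusted p under 0.05), 9 (43) for the difference in change between formats, and an overlap of 179 (514). The fit of the 8 arrays of scan day 2 gave 9 (43) for that difference, being the same arrays. With no filter on dim probes limma called 13502 (7252) in EB day 4 against undifferentiated cells and 7619 (2246) against day 3, 70.1% and 73.8% of them higher. The same setting gave 569 (962) in EB day 3 against day 1, 1 (12) and 375 (585) for EB against ML at days 1 and 3, 6 (43) for the difference in change and an overlap of 282 (514). The strict filter, which tests fewer genes, gave 637 (962), 0 (12, 1219 at an unadjusted p under 0.05) and 26 (43) for EB day 3 against day 1, EB against ML at day 1 and the difference in change. EB against ML at day 1 had 23 calls (12) with the mean of probes, 5 with the replicate block and 20 with the trended prior.

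With 1 array left out, a lone array is assumed to vary like the other groups. Called genes against undifferentiated cells ranged from 204 (without EB day 1 replicate 1) to 2571 (without undifferentiated replicate 1) in EB day 1, from 1832 (without EB day 3 replicate 2) to 3511 (without undifferentiated replicate 1) in EB day 3, from 4660 (without EB day 4 replicate 1) to 5983 (without undifferentiated replicate 1) in EB day 4, from 292 (without ML day 1 replicate 2) to 3477 (without undifferentiated replicate 1) in ML day 1 and from 2378 (without undifferentiated replicate 2) to 5728 (without ML day 3 replicate 2) in ML day 3. They ranged from 104 (without EB day 1 replicate 2) to 996 (without EB day 3 replicate 1) in EB day 3 against day 1, from 379 (without ML day 1 replicate 2) to 4765 (without ML day 3 replicate 2) in ML day 3 against day 1 and from 338 (without EB day 3 replicate 1) to 1613 (without EB day 3 replicate 2) in EB day 4 against day 3. EB against ML ranged from 1 (without EB day 1 replicate 1 or ML day 1 replicate 2) to 5 (without ML day 1 replicate 1) at day 1 and from 111 (without EB day 3 replicate 2) to 2475 (without ML day 3 replicate 2) at day 3, the difference in change from 0 (without EB day 1 replicate 1 or EB day 1 replicate 2 or ML day 1 replicate 2) to 298 (without ML day 3 replicate 2), with 1244 to 1306 at an unadjusted p under 0.05 where limma called 0, and the overlap from 46 (without EB day 1 replicate 2) to 532 (without ML day 3 replicate 2). Totals of called lists are not given, since most of the 11 comparisons do not use the omitted array. Of 120 list tests called by camera, 22 were not called with the strict filter, 15 with normexp background, 10 with no filter, 9 with quantile normalization or with the authors' values and 51 by fry. Fry called 91 list tests in all and camera 4 with an estimated correlation, and the cause was not tested.

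Among single gene results named in the text, none was called with opposite directions under different settings. The numbers of named-gene results that stayed on their side of the threshold and that lost their call were 180 and 2 with quantile normalization, 179 and 2 with the authors' values, 178 and 2 with normexp background, 176 and 9 with no filter and 150 and 35 with the compared groups alone. Among leave-one-out fits 681 such results stayed and 79 lost their call. Calls were also gained with 1 array left out, for T in EB day 1 and Nanog in ML day 3 against undifferentiated cells. Sox17 in ML day 3 against day 1 and Eomes in EB against ML at day 3 gained calls too. Slide as a block was not run, because slides and group means leave no term for it. Signal over background limits folds of genes dim in 1 group, given as bounds, with 52.1% to 63.8% of spots well above background.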

Other observations

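The tests of gene lists here were planned, and the choice of which to describe was made after their results were seen. Hypoxia and glycolysis genes, which respond to low oxygen, were lower at day 1 than in undifferentiated cells, with Vegfa (-3.28 ± 0.62) and Slc2a3 (-2.32 ± 0.45) in EB day 1. Of 25 measured, the EB day 1 comparison had 6 lower and 19 not called, and 9 lower adjusted over the list alone (median -1.16, camera adjusted p = 2.55e-05, adjusted p = 0.52 with an estimated correlation, not called with fry), and ML day 1 had 1 higher, 9 lower and 15 not called, and 2 higher and 14 lower adjusted over the list alone (median -1.35, camera adjusted p = 4.53e-06, adjusted p = 0.756 with an estimated correlation, not called with fry). From EB day 1 to day 3 the list was higher again, with 2 higher and 23 not called, and 6 higher adjusted over the list alone (median 0.88, camera adjusted p = 7.7e-07, adjusted p = 0.374 with an estimated correlation, not called with fry) and Egln1 (2.36 ± 0.36) rising. In ML day 1 Vegfa (-3.49 ± 0.62) fell as well, and ML day 3 against undifferentiated cells had 8 lower and 17 not called, and 11 lower adjusted over the list alone (median -0.89, camera adjusted p = 0.00126, adjusted p = 0.59 with an estimated correlation, up to 0.0644 without undifferentiated replicate 2, not called with fry). Calls ended for Vegfa in EB without undifferentiated replicate 2 or EB day 1 replicate 1 or 2 (adjusted p up to 0.104), Slc2a3 without undifferentiated replicate 2 or EB day 1 replicate 1 or 2 (adjusted p up to 0.0881), Egln1 without EB day 1 replicate 1 or 2 or EB day 3 replicate 2 (adjusted p up to 0.0859) and Vegfa in ML without undifferentiated replicate 2 or ML day 1 replicate 1 or 2 (adjusted p up to 0.070).

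Genes that act on DNA methylation changed in ML between days 1 and 3, where the methylcytosine dioxygenase gene Tet1 (-1.61 ± 0.23) and the methyltransferase cofactor gene Dnmt3l (-1.84 ± 0.33) fell. Of 11 measured, the list had 5 lower and 6 not called, and 7 lower adjusted over the list alone (median -0.95, camera adjusted p = 0.00859, adjusted p = 0.347 with an estimated correlation). Tet1 (-3.11 ± 0.23) and Dnmt3l (-4.02 ± 0.33) were lower and Tet3 (4.23 ± 0.39) higher in EB day 4 than in undifferentiated cells. Of 11 measured trophectoderm genes, EB day 3 against EB day 1 had 3 higher and 8 not called, and 5 higher adjusted over the list alone (median 1.63, camera adjusted p = 0.000102, adjusted p = 0.268 with an estimated correlation, not called with fry), the homeobox gene Cdx2 (3.54 ± 0.55) among them. Snai1 (3.44 ± 0.39), a repressor of E-cadherin, rose from EB day 1 to day 3. There the 16 measured genes of the epithelial and mesenchymal list included 2 higher and 14 not called, and 3 higher adjusted over the list alone (median 0.56, camera adjusted p = 0.00853, adjusted p = 0.268 with an estimated correlation, not called with fry). That call ended without EB day 3 replicate 2. Fitted alone, ML days 1 and 3 gave no call of Tet1, and EB days 1 and 3 none of Cdx2. Calls ended for Dnmt3l without ML day 1 replicate 2 or ML day 3 replicate 1 (adjusted p up to 0.0754) and Cdx2 without EB day 1 replicate 2 or EB day 3 replicate 2 (adjusted p up to 0.0888).

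Germ cell genes were lower in EB day 4 than in undifferentiated cells, with Mael (-5.06 ± 0.62) and Dppa3 (-4.49 ± 0.69), and of 12 measured the list had 1 higher, 9 lower and 2 not called, and 1 higher and 9 lower adjusted over the list alone (median -2.94, camera adjusted p = 0.0013, adjusted p = 0.299 with an estimated correlation). The p53 targets had a lower median in EB than in ML at day 3 (median -0.82, camera adjusted p = 8.66e-05, adjusted p = 0.196 with an estimated correlation), with no member called in limma. The list of sex-linked genes (3 measured) was called higher by camera in EB day 1 and ML day 1 than in undifferentiated cells (adjusted p = 0.0283 and 0.0288, adjusted p = 0.486 and 0.729 with an estimated correlation, up to 0.0983 and 0.171 without undifferentiated replicate 1), but not with normexp background, no filter or the strict filter. The neuroectoderm list was not called by camera in any comparison, whereas fry called it in EB day 3, EB day 4 and ML day 3 against undifferentiated cells and in ML day 3 against ML day 1 (adjusted p = 0.000676 to 0.0253 by fry), and its median in EB day 4 against undifferentiated cells was -0.29 with 3 higher, 5 lower and 5 not called, and 4 higher and 6 lower adjusted over the list alone among 13 measured genes.

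A list's median, mean and camera direction differed in sign in 28 of 286 tests, none of them called. These include the definitive endoderm list in ML day 3 against undifferentiated cells (median -0.26, mean 1.08) and the LIF and STAT3 targets in ML day 3 against ML day 1 (median 0.46, mean -0.02).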
